A study of Mus musculus with 16 samples.

How the data were processed

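RNA was measured by sequencing in livers of mice kept on a high-fat diet. Per the labels, total RNA was taken with an RNeasy kit and DNase I, libraries were made after polyA enrichment, and paired reads of 150 bases were sequenced on a NovaSeq instrument. All 16 libraries are labelled with the conditional genotype written J1 J2 lf/lf on a C57/Bl6J background. The group of each library was read from its title: 5 libraries named GFP, which serve as controls, 5 named Cre, whose hepatocytes the series text names for the 7a isoforms of JNK1 and JNK2, and 6 named Flpo, named for the 7b isoforms. The replicate numbers also come from the titles. The titles carry a separate number for each library, and the labels do not say outright that each comes from a different mouse, so p-values measure the spread between these libraries. These numbers run in blocks by group, so a batch of animals or of harvest cannot be separated from the group.

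The authors deposited a table of estimated counts per gene and a table of TPM, which is abundance scaled for gene length and library total, for the same libraries. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with STAR to mm10, with no version stated. The program that made the deposited estimated counts, its annotation and its use of strand are not given in the sources used here. Of the deposited count values, 31.7% were not whole. In 10835 genes with more than 20 counts in every library, each deposited count was the deposited TPM multiplied by 1 factor per gene and 1 per library, with a largest deviation of 1.07e-09 on the log2 scale. The counts are therefore TPM scaled back to each library with 1 length per gene. Reads shared between near-identical genes, such as the Mup genes, or between overlapping and antisense genes may have been split between them, so single members of such families are uncertain. The table has 55487 rows, and 114 symbols stand on more than 1 row, 234 rows in all. Such rows were kept separate, and a symbol named in a gene list stands for its most abundant row.

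Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 13905 genes. Libraries were scaled with TMM factors. All 16 libraries entered 1 quasi-likelihood fit with robust estimation, and the 3 comparisons between groups were contrasts of that fit. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values are counts scaled to the library total with its TMM factor and are given as mean ± SD.

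Before the data were examined, 30 gene lists were fixed, which cover pathways of the liver and markers of its cell types. The lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison. Camera with an estimated correlation and fry were run beside it. No list passed with an estimated correlation in any of the 3 comparisons. With fry, 8 lists passed in Cre against GFP, 0 in Flpo against GFP and 10 in Flpo against Cre. Fry's test without regard to direction passed 23, 1 and 26 lists in that order. Counts of list members are given from the adjustment over all genes and from an adjustment over the list alone.

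The rule for named genes was also fixed beforehand. It takes Mapk8, Mapk9 and 9 sentinel genes. In each comparison it adds changed genes with a mean CPM of at least 1 whose libraries all lie on their own side of the other group's median: the 6 with the largest rise, the 6 with the largest fall and the 3 with the smallest adjusted p. It also adds up to 4 members with the smallest adjusted p from each list that passed or had at least 3 changed members. Where fewer than 6 genes pass, the 5 with the smallest p are named. The rule gave 103 names in Cre against GFP, 48 in Flpo against GFP and 114 in Flpo against Cre. The text takes its examples from these, and those whose call held across the alternatives were preferred, so the examples are firmer than the full set. Results for some of the named genes are not reported here. Effects of the alternatives on the full set are counted in the closing section.

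The alternatives set beforehand were DESeq2-type size factors, library totals alone, no low-count filter, a filter of CPM of at least 1 in at least 5 libraries, DESeq2 1.42.0, limma-voom without and with sample quality weights, only the 2 groups compared, the replicate number as a block, 1 surrogate variable from sva 3.50.0, limma on log2(TPM + 1) of the deposited TPM, each library left out in turn, and stricter thresholds. The block was fitted without Flpo replicate 6, whose number no other library carries. Added after seeing the data were an offset for gene length and GC content, the removal of the 50 most abundant genes and all Mup genes before scaling, and a score of clock genes as a covariate. Where the text counts the settings in which a gene passed, fits with a clock score are left out. Length and GC values were available for 98.7% of the genes tested.

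Total counts per library ranged from 27929426 to 36043249. The edgeR test was tested on simulated counts with 200 changed genes, drawn from genes with a mean CPM of at least 1 in GFP. For Cre against GFP it recovered 35.8% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 6 false calls among 13615 genes. For Flpo against GFP the shares were 32.8%, 77.6% and 90.9% with 7 false calls among 13595 genes, and for Flpo against Cre 23.9%, 77.6% and 90.9% with 5 among 13628. Such shares depend on how many genes change, so they hold for 200 changed genes. On the simulated counts for Cre against GFP, DESeq2 made 28 false calls among 13905 genes and limma-voom 3 among 13615. No pair of libraries agreed within sampling noise, as the lowest chi-square per degree of freedom between libraries of a group was 30.6, so every library counted as 1 replicate. Gene positions come from the GENCODE annotation of GRCm38, the same assembly as mm10, matched by symbol. Isoform abundance and reads were not analysed here.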

Results

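Liver RNA of mice on a high-fat diet was sequenced in 16 libraries to compare groups of livers that are named for alternative splice isoforms of the stress kinases JNK1 and JNK2 in hepatocytes. The kinases are encoded by Mapk8 and Mapk9, whose transcripts use either of a pair of mutually exclusive exons. There were 5 GFP control libraries, 5 Cre libraries named for the 7a isoforms and 6 Flpo libraries named for the 7b isoforms. Cre and Flpo are DNA recombinases that act on conditional alleles. Total counts per library ranged from 27929426 to 36043249, and 17024 to 18231 genes had a count above 0.

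The targeted genes were measured at the gene level in every library. Mapk8 lies on chromosome 14 from 33377898 to 33447158 in GRCm38, on the minus strand. Its abundance was 11.7 ± 3.04 CPM in GFP (SD, n = 5), 11.4 ± 2.44 in Cre (n = 5) and 13.5 ± 0.824 in Flpo (n = 6). Mapk9 lies on chromosome 11 from 49846751 to 49886421, on the plus strand. It stood at 42.7 ± 14.1 CPM in GFP, 33.1 ± 5.49 in Cre and 46.3 ± 4.21 in Flpo. Neither gene differed past the threshold in any comparison. The smallest adjusted p of edgeR's quasi-likelihood test was 0.0784, for Mapk9 in Flpo against Cre, with a log2 fold change of 0.48 and a standard error of 0.18. That difference passed in 8 of 29 alternative settings, among them the fits without GFP replicate 1, without GFP replicate 3 and without Cre replicate 4 (adjusted p = 0.0472, 0.0181 and 0.0402). The clock score as a covariate is not among the 29, and with it the difference did not pass (adjusted p = 0.846). Its log2 fold change with that covariate was 0.61, so the lost call does not tie the difference to time of day. Mapk9 also passed in Cre against GFP without GFP replicate 3, at a log2 fold change of -0.52 and an adjusted p of 0.0304.

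In Mapk8 the mutually exclusive exons span 33390242 to 33390313 and 33390673 to 33390744, each 72 bases long, and each is used by 2 of 5 annotated coding transcripts. In Mapk9 they span 49873836 to 49873907 and 49874264 to 49874335, also 72 bases each, and are used by 4 and 3 of 7 coding transcripts. No annotated transcript holds both. A count summed over the gene cannot show which of these exons was used, so the levels of Mapk8 and Mapk9 do not check the isoform label of a library.

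**Figure D1:**
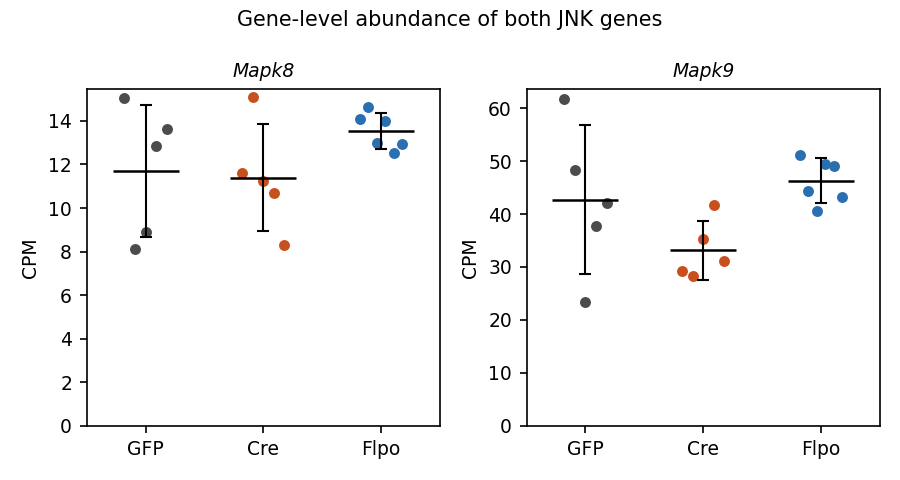
Abundance of Mapk8 and Mapk9 per liver library, in CPM from 0, with points for libraries and lines with bars for the mean and SD of 5 GFP, 5 Cre and 6 Flpo libraries. The groups overlap for both genes, and GFP has the widest spread for Mapk9, at 42.7 ± 14.1 CPM.

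Over the 500 most variable genes, the first principal component held 33.1% of the variance and the second 9.36%. On the first component the 5 Cre libraries lay between 20.3 and 33.2, and the GFP and Flpo libraries between -20.8 and -3.74. Transcripts of the major urinary proteins (Mup genes) took 5.65% to 13.8% of the counts in Cre, 2.24% to 3.91% in GFP and 1.95% to 6.49% in Flpo. The share of mitochondrial transcripts was 3.73% to 5.56% over all libraries.

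**Figure D2:**
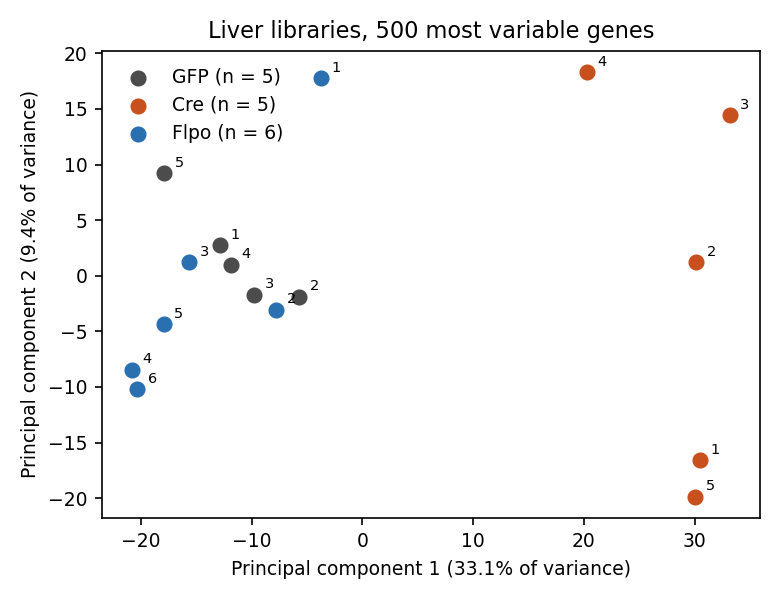
Position of each liver library on the first principal component (33.1% of variance) and the second (9.36%) of log2 CPM of the 500 most variable genes, with replicate numbers beside the points. On the first component the Cre libraries lie between 20.3 and 33.2, and all GFP and Flpo libraries between -20.8 and -3.74.

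The comparison of Cre with GFP asks what differs in livers named for the 7a isoforms. Plin4, a coat protein of lipid droplets, fell from 50.7 ± 13.8 CPM in GFP to 8.58 ± 2.16 in Cre (n = 5 each), and Cd36, a fatty acid transporter, from 224 ± 52.1 to 33.9 ± 18.6. Cyp7b1, a hydroxylase of oxysterols that is usually higher in male liver, rose from 101 ± 21.5 to 461 ± 150 CPM. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 fell, as did Lgals1, which encodes galectin-1, from 71.4 ± 3.74 to 8.01 ± 2.75 CPM.

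In all, 1328 of 13905 genes changed in edgeR's quasi-likelihood test, 552 higher and 776 lower in Cre, and 440 of them by at least 2-fold. The smallest adjusted p values belonged to Lgals1 (log2 fold change -3.15, SE 0.22, adjusted p = 1.07e-06), Plin4 (-2.56, SE 0.20, 1.32e-06) and Rapgef4, an exchange factor activated by cyclic AMP (1.35, SE 0.12, 4.57e-06). Lgals1 lies on chromosome 15 from 78926725 to 78930465, Plin4 on chromosome 17 from 56100591 to 56109803 and Rapgef4 on chromosome 2 from 71981240 to 72257474. The split between higher and lower genes depended on scaling. Library totals alone gave 300 higher and 1656 lower, log2(TPM + 1) with limma gave 188 and 1909, and an offset for gene length and GC content gave 805 and 710. Library totals and TPM moved the median log2 fold change of all genes to -0.14 and -0.15. A fit of only these groups called 834 genes, and a score of clock genes as a covariate, chosen after seeing the data, left 238. Among genes named here for this comparison, Pklr, Cyp4a31, Hadh, Enho, Gstp1, Asns and Sox9 were not called with that covariate, although Cyp4a31 had a log2 fold change of 1.82 with it and 1.73 without, Enho 1.87 and 2.10, Pklr -0.88 and -1.08, Gstp1 1.41 and 1.82, Hadh -0.40 and -0.55, Asns 2.83 and 4.50 and Sox9 0.73 and 1.31.

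Of 22 genes of lipid droplets and steatosis, 7 fell and 3 rose, with 9 and 4 when adjusted over the list alone (camera, adjusted p = 0.0114, down). The adjusted p was 0.443 with an estimated correlation, and the list's median log2 fold change was slightly positive at 0.04 while its mean was -0.63. The median was -0.12 with library totals alone and -0.44 on log2(TPM + 1). Besides Plin4 and Cd36 the falls included Pparg, a nuclear receptor that drives fat storage (log2 fold change -1.35, SE 0.19, adjusted p = 0.000223), and Cfd, which encodes adipsin (-2.93, SE 0.37, 0.000136). Of 24 lipogenesis genes, 8 fell and 2 rose, with the same counts adjusted over the list alone (camera, adjusted p = 0.0137, down, and adjusted p = 0.443 with an estimated correlation). The lipogenic regulator Thrsp fell from 111 ± 65.4 to 11.2 ± 5.61 CPM and liver pyruvate kinase (Pklr) from 159 ± 19.2 to 75.1 ± 27.5. Fatty acid synthase (Fasn) stood at 158 ± 37.8 and 153 ± 64.7 CPM and did not pass.

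Fatty acid oxidation and ketogenesis rose as a list of 37, with 7 members higher and 1 lower, and 9 and 1 adjusted over the list alone (camera, adjusted p = 0.00125, and adjusted p = 0.659 with an estimated correlation). Its median log2 fold change was 0.18, and -0.02 on log2(TPM + 1), where 2 members were higher and 1 lower. Ehhadh, an enzyme of peroxisomal oxidation, rose from 503 ± 92.2 to 1770 ± 997 CPM, and Cyp4a31 from 24.1 ± 8.80 to 80.1 ± 43.4, while the mitochondrial dehydrogenase Hadh fell (log2 fold change -0.55, SE 0.10, adjusted p = 0.00249). Ppara, the receptor that controls this programme, was not called at 0.40 (SE 0.17, adjusted p = 0.162). Fgf21, a fasting hormone of the liver, missed the threshold at 1.45 (SE 0.44, adjusted p = 0.0524) and passed it in 8 of 29 alternative settings, including those without GFP replicate 4, Cre replicate 3, Cre replicate 4 or Flpo replicate 6 (adjusted p = 0.0425, 0.0122, 0.0323 and 0.0499). With the clock score, which is not among the 29, Fgf21 did not pass (log2 fold change 0.91, adjusted p = 0.55).

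Of 27 genes of insulin and growth hormone signalling, 8 rose and 1 fell, with 11 and 2 adjusted over the list alone (camera, adjusted p = 0.000585, up, and adjusted p = 0.0593 with an estimated correlation). Igfbp2, a binding protein of insulin-like growth factors, rose from 271 ± 44.4 to 1154 ± 275 CPM. Enho, which encodes adropin, rose by 2.10 on the log2 scale (SE 0.35, adjusted p = 0.00172), the insulin receptor substrate Irs2 by 1.63 (SE 0.29, 0.00204) and Grb14, an adaptor that binds the insulin receptor, by 0.49 (SE 0.09, 0.00182). Of 22 genes of gluconeogenesis and glycogen, 2 rose and 4 fell, with 6 each adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.875). Pck1, which catalyses a committed step of glucose production, rose from 1374 ± 615 to 3411 ± 773 CPM.

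By median log2 fold change, the largest shift among the 30 lists in Cre against GFP was in male-biased genes. Of 24 male-biased liver genes, 19 rose and 0 fell, with 22 higher adjusted over the list alone, and the median log2 fold change was 1.87 (camera, adjusted p = 1.74e-19, and adjusted p = 0.272 with an estimated correlation). Members included Elovl3, a fatty acid elongase (log2 fold change 1.89, SE 0.26, adjusted p = 3e-04), the glutathione transferase Gstp1 (1.82, SE 0.27, 0.000518) and Serpina1e (4.56, SE 0.66, 0.000747). Of 17 female-biased genes, 6 fell and 0 rose, with 6 lower and 1 higher adjusted over the list alone (camera, adjusted p = 5.35e-05, and adjusted p = 0.443 with an estimated correlation). Cyp2b9 fell from 175 ± 99.05 to 4.61 ± 5.37 CPM, the transporter gene Slc22a27 from 10.9 ± 2.68 to 0.344 ± 0.284 and the sulfotransferase gene Sult2a7 from 3.42 ± 1.41 to 0.885 ± 0.356. The highest count of the female transcript Xist in any library was 3, and the lowest of the Y-linked gene Ddx3y was 1216.

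**Figure D3:**
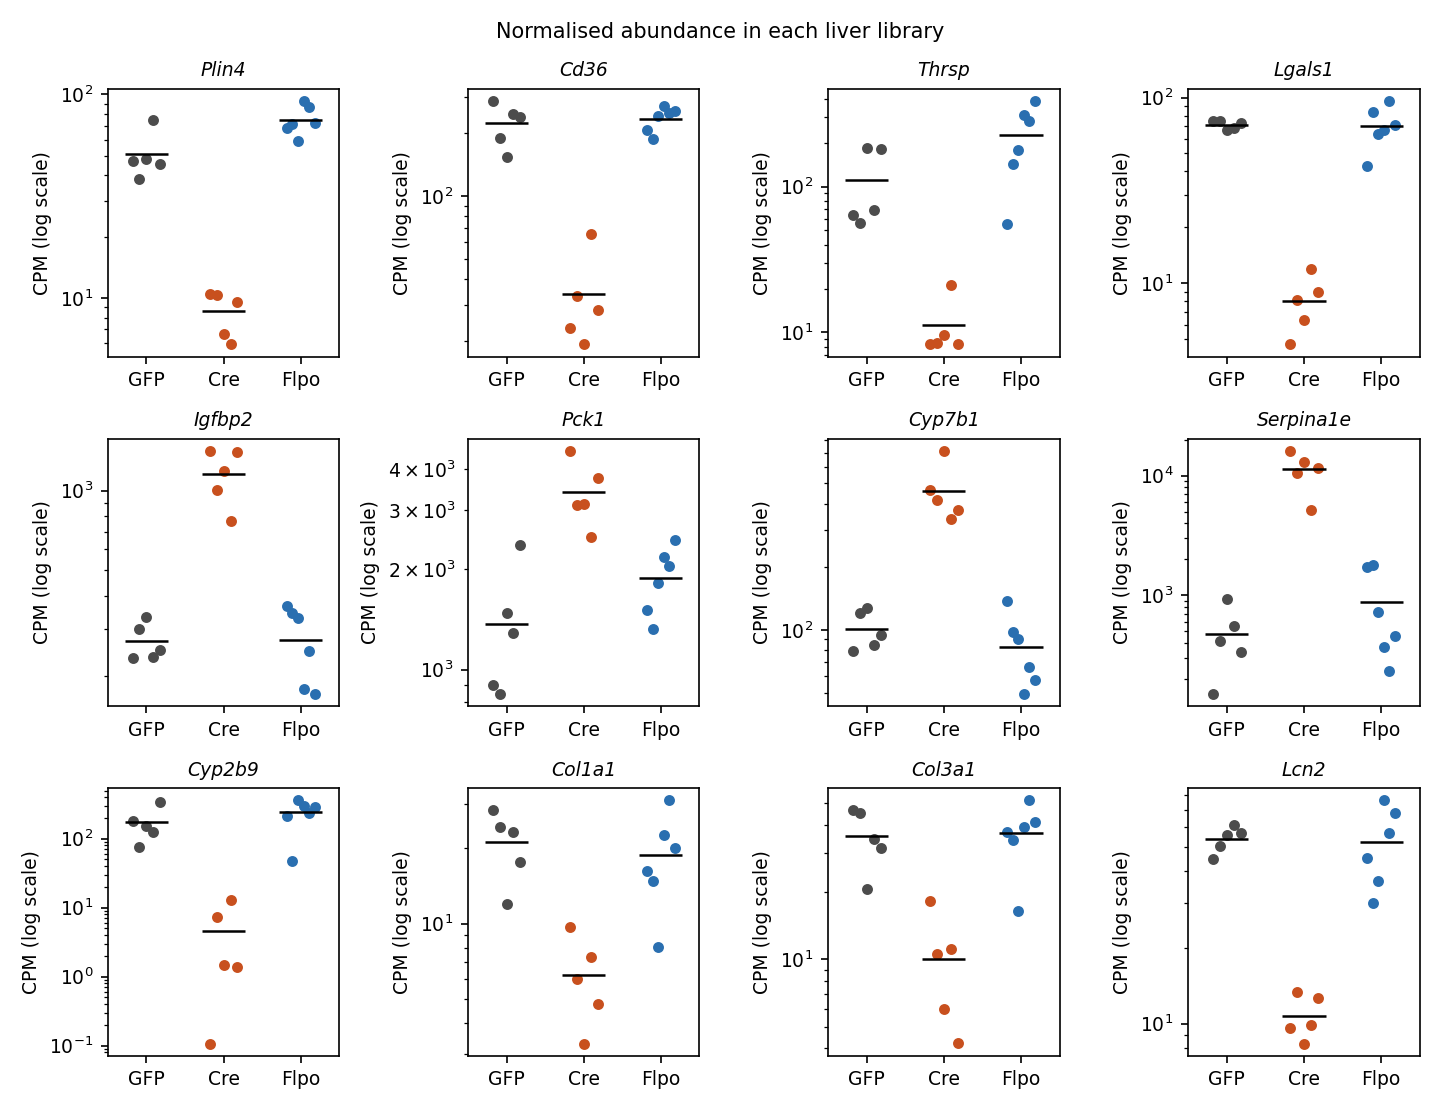
Abundance of 12 genes in each liver library, in CPM on log axes, with points for libraries and lines for group means of 5 GFP, 5 Cre and 6 Flpo libraries. Cre libraries lie apart from both other groups, below them for genes such as Plin4 (8.58 ± 2.16 CPM) and Lgals1 (8.01 ± 2.75) and above them for Igfbp2 (1154 ± 275).

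Markers of stellate cells and fibrosis fell, with 9 of 31 lower and 0 higher, and 12 lower adjusted over the list alone (camera, adjusted p = 1.78e-05, and adjusted p = 0.443 with an estimated correlation). Col1a1 fell from 21.2 ± 6.45 to 6.23 ± 2.44 CPM, Col1a2 from 23.3 ± 5.62 to 8.22 ± 2.20 and Col3a1 from 35.8 ± 10.6 to 10.03 ± 5.47. Endothelial markers passed upward (adjusted p = 0.00125) with 1 of 23 members called higher and 0 adjusted over the list alone, and with an estimated correlation the adjusted p was 0.51. Markers of lymphocytes and neutrophils passed upward (adjusted p = 0.0238, and adjusted p = 0.443 with an estimated correlation) with 2 of 18 higher, 3 adjusted over the list alone. The lymphocyte call was lost without GFP replicate 1, 2 or 3 or Cre replicate 1 or 2, at adjusted p up to 0.0975. Kupffer cell markers did not pass, with 0 of 16 called by either adjustment (adjusted p = 0.415), nor did markers of lipid-associated macrophages, with 2 of 20 higher and 1 lower, 2 and 3 adjusted over the list alone (adjusted p = 0.32). Cholangiocyte markers had 1 of 14 higher and 2 lower by either adjustment (adjusted p = 0.875). The cholangiocyte and periportal marker Sox9 rose by 1.31 on the log2 scale (SE 0.26, adjusted p = 0.00455) and the keratin gene Krt8 fell by 0.53 (SE 0.08, 0.000683). The macrophage gene Adgre1 and the chemokine gene Ccl2 were not called, at log2 fold changes of -0.38 each (SE 0.26 and 0.44, adjusted p = 0.396 and 0.644).

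Genes of the unfolded protein and integrated stress response rose with 4 of 28 higher, 6 adjusted over the list alone (adjusted p = 0.000585, and adjusted p = 0.443 with an estimated correlation). Asns, asparagine synthetase, rose from 0.952 ± 0.833 to 21.6 ± 22.0 CPM, a call that limma-voom did not make (adjusted p = 0.0768). NRF2 and oxidative stress genes fell with 6 of 25 lower and 2 higher, 8 and 2 adjusted over the list alone (adjusted p = 0.0205, and adjusted p = 0.443 with an estimated correlation). The glutathione transferase gene Gsta1 fell from 4.47 ± 0.720 to 0.244 ± 0.211 CPM, whereas Gstp1, which is also male-biased, rose. Oxidative phosphorylation passed downward with 1 of 30 lower and 0 adjusted over the list alone (adjusted p = 0.00561, and adjusted p = 0.659 with an estimated correlation), and lost its call without GFP replicate 3 or Cre replicate 4, at adjusted p up to 0.0756. Periportal hepatocyte genes passed upward with 3 of 22 higher and 0 lower, 5 and 1 adjusted over the list alone (adjusted p = 0.0226, and adjusted p = 0.659 with an estimated correlation), and lost the call without GFP replicate 2, GFP replicate 4 or Cre replicate 1, at adjusted p up to 0.532.

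The remaining lists did not pass. The acute phase list had 5 of 27 lower and 0 higher, 5 and 3 adjusted over the list alone (adjusted p = 0.0678). It passed with no low-count filter (adjusted p = 0.0145) and without GFP replicate 1, GFP replicate 2, Cre replicate 1, Cre replicate 2 or Flpo replicate 2, at adjusted p down to 0.0259. Its members Lcn2, lipocalin-2, fell from 53.8 ± 6.26 to 10.8 ± 2.14 CPM and Orm2 from 22.0 ± 7.44 to 5.56 ± 1.40. Of 20 clock genes 5 fell and 1 rose, 7 and 3 adjusted over the list alone (adjusted p = 0.283). Camera tests for a shift in 1 direction, so clock genes of opposite phase can cancel, and this p does not show an unchanged clock. The bile acid list had 4 of 26 higher and 4 lower, 5 and 6 adjusted over the list alone (adjusted p = 0.991), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was not called (148 ± 62.4 and 106 ± 39.7 CPM, adjusted p = 0.334). The lipoprotein list had 3 of 24 higher and 4 lower, 3 and 5 adjusted over the list alone (adjusted p = 0.927), and its receptor gene Vldlr fell by 2.75 on the log2 scale (SE 0.44, adjusted p = 0.00104). Xenobiotic metabolism had 1 of 23 higher and 4 lower, 1 and 6 adjusted over the list alone (adjusted p = 0.0621). It passed with no low-count filter (adjusted p = 0.0142) and without GFP replicate 1, 2 or 4, Cre replicate 4 or Flpo replicate 1, at adjusted p down to 0.0113. Pericentral hepatocytes had 3 of 23 higher and 1 lower, 3 and 3 adjusted over the list alone (adjusted p = 0.927).

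Further lists are to be read beside the share of all genes called in Cre against GFP, which was 9.55%. The JNK pathway list had 2 of 19 lower, 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.875). AP-1 and immediate early genes had 0 of 17 called by either adjustment (adjusted p = 0.321), and the AP-1 subunit Jun stood at -0.21 (SE 0.31, adjusted p = 0.726). The interferon response had 0 of 33 called by either adjustment (adjusted p = 0.691). Cytokines and chemokines had 1 of 23 lower and the cell cycle 1 of 25 lower, each also adjusted over the list alone (adjusted p = 0.991 and 0.0912). The cell cycle list passed with no low-count filter (adjusted p = 0.0144). Cholesterol synthesis had 1 of 25 higher by either adjustment (adjusted p = 0.927). Transcripts of blood, pancreas and fat had 1 of 6 lower, 4 adjusted over the list alone (adjusted p = 0.114). Median, mean and test differed in sign for the lists of the JNK pathway (0.05, -0.08, down), cholesterol synthesis (-0.03, 0.08, up), gluconeogenesis (0.02, 0.11, down), lipoprotein (0.05, -0.10, up), cytokines (0.02, 0.02, down), interferon (0.01, 0.03, down) and pericentral hepatocytes (0.05, -0.01, up).

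The comparison of Flpo with GFP asks the same of livers named for the 7b isoforms. Only 4 genes changed, all lower in Flpo (n = 6) than in GFP (n = 5). Rec8, which encodes a meiotic cohesin subunit, fell from 3.97 ± 1.43 to 0.634 ± 0.297 CPM. Pde9a, a phosphodiesterase of cyclic GMP, fell from 13.6 ± 2.70 to 6.76 ± 1.44, Smarcd1, a subunit of the SWI/SNF chromatin remodelling complex, from 8.57 ± 1.61 to 4.52 ± 0.332, and the gene model Gm19696 from 9.88 ± 2.96 to 4.70 ± 0.460. Plin4, Cd36, Igfbp2 and the collagen genes, which changed in Cre, were not called in Flpo, as Col1a1 at -0.17 (SE 0.31, adjusted p = 0.887).

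By edgeR's quasi-likelihood test the adjusted p was 0.0153 for Rec8 (log2 fold change -2.64, SE 0.37) and 0.0196 for Pde9a (-1.01, SE 0.15), Smarcd1 (-0.92, SE 0.14) and Gm19696 (-1.07, SE 0.17). Rec8 lies on chromosome 14 from 55618037 to 55625395, Pde9a on chromosome 17 from 31386210 to 31476310 and Smarcd1 on chromosome 15 from 99702129 to 99713991. At an unadjusted p under 0.05 there were 1353 genes, 645 higher and 708 lower, where chance alone gives 695 on average. Genes are correlated, so such a count can lie far from 695 without a group effect. With the clock score as a covariate, which itself differed between the groups, the count was 635. DESeq2 called 69 genes, limma-voom 2 and limma-voom with quality weights 24, and the clock score as a covariate or the replicate block left 0. In simulated counts for Cre against GFP, DESeq2 made 28 false calls where edgeR made 6, so its 69 genes are less certain. The block was fitted without Flpo replicate 6, and its effect cannot be told apart from the loss of that library. The count was 0 without GFP replicate 1, GFP replicate 2 or Flpo replicate 3, 4 or 6, 1 without GFP replicate 3, and 15 without GFP replicate 5 or Flpo replicate 1.

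Of the 30 lists, 8 passed camera in Flpo against GFP although none of their members was called over all genes. Gluconeogenesis and glycogen passed upward (adjusted p = 0.000418, and adjusted p = 0.245 with an estimated correlation), with 2 of 22 members higher adjusted over the list alone. Its examples were glycogen synthase, Gys2, at 126 ± 18.9 and 178 ± 23.9 CPM, and pyruvate carboxylase, Pcx, at 787 ± 40.3 and 986 ± 74.7. The circadian clock list passed upward (adjusted p = 0.00265, and adjusted p = 0.245 with an estimated correlation), with 5 of 20 higher and 2 lower adjusted over the list alone. Arntl, which encodes the clock activator BMAL1, stood at 3.92 ± 1.46 and 1.79 ± 0.511 CPM, and Tef at 115 ± 34.2 and 171 ± 25.5. Transcripts of blood, pancreas and fat passed downward (adjusted p = 1.96e-05, and adjusted p = 0.245 with an estimated correlation), with 4 of 6 lower adjusted over the list alone. These were globin genes such as Hba-a1, at 199 ± 67.7 and 99.8 ± 34.4 CPM, and Hbb-bt, at 46.9 ± 14.1 and 23.6 ± 9.79. Hbb-bt passed over all genes without Flpo replicate 1 (adjusted p = 0.0108), and both passed with DESeq2 (adjusted p = 0.00843 for Hbb-bt and 0.0147 for Hba-a1). DESeq2 made more false calls than edgeR in the simulated counts.

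Another 5 lists passed in Flpo against GFP with no member called by either adjustment, each at an adjusted p of 0.897 with an estimated correlation. Upward were the unfolded protein and integrated stress response (adjusted p = 0.00265), xenobiotic metabolism (0.0122), pericentral hepatocytes (0.0305) and Kupffer cells (0.0353), and downward was cholesterol synthesis (0.023). Members with values were the pericentral gene Glul, glutamine synthetase, at 1025 ± 113 and 1353 ± 127 CPM, the Kupffer cell receptor Marco at 4.24 ± 1.44 and 10.6 ± 9.19, and Hmgcs1, of the cholesterol pathway, at 358 ± 93.7 and 247 ± 147. The stress response lost its call without Flpo replicate 1 (adjusted p = 0.0637), and xenobiotic metabolism without GFP replicate 2 or Flpo replicate 4, at adjusted p up to 0.125. Cholesterol synthesis lost its call under the replicate block (adjusted p = 0.41) and without GFP replicate 2, GFP replicate 5, Flpo replicate 4 or Flpo replicate 6, at adjusted p up to 0.604. The pericentral list lost its call without GFP replicate 1, 2 or 4 or Flpo replicate 1, 3 or 4, and the Kupffer cell list without GFP replicate 1, 2 or 3 or Flpo replicate 1, 3, 4 or 5, at adjusted p up to 0.156 and 0.353. In the other 22 lists no member was called, by either adjustment, in Flpo against GFP. Of these, fatty acid oxidation passed without GFP replicate 4 or Flpo replicate 4, cytokines without GFP replicate 4, GFP replicate 5 or Flpo replicate 2, acute phase and male-biased genes without Flpo replicate 1, periportal hepatocytes without GFP replicate 3 and endothelial markers without Flpo replicate 2. Their lowest adjusted p were 0.0107, 0.00979, 0.0186, 0.0493, 0.0417 and 0.0136 in that order. Median, mean and test differed in sign for male-biased genes (0.17, 0.36, down), stellate cells (-0.01, -0.00466, up) and cholangiocytes (-0.10, 0.11, up).

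The direct comparison of Flpo with Cre tests whether the isoform groups differ from each other. Plin4 was higher in Flpo and stood at 75.1 ± 12.3 CPM in Flpo (n = 6) against 8.58 ± 2.16 in Cre (n = 5), Cd36 at 236 ± 31.4 against 33.9 ± 18.6 and Thrsp at 226 ± 121 against 11.2 ± 5.61. Cyp7b1 was lower in Flpo, at 83.1 ± 32.3 against 461 ± 150 CPM, and so was Fgf21, at 8.07 ± 2.72 against 34.7 ± 21.7. The collagen gene Col3a1 was higher in Flpo, at 36.7 ± 11.5 against 10.03 ± 5.47 CPM.

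In edgeR's quasi-likelihood test 1906 genes changed, 1036 higher and 870 lower in Flpo, and 582 of them by at least 2-fold. The smallest adjusted p values belonged to Plin4 (log2 fold change 3.13, SE 0.20, adjusted p = 1.04e-07), Lgals1 (3.13, SE 0.22, 4.33e-07) and Ppl, which encodes periplakin (2.28, SE 0.20, 5.62e-06). Here too the split depended on scaling. Library totals alone gave 1810 higher and 454 lower, log2(TPM + 1) with limma gave 2408 and 281, and the median of all genes moved to 0.13 and 0.17. With the clock score as a covariate, chosen after seeing the data, 8 genes were left, among them Plin4, Lgals1 and Ppl but no other gene named for this comparison here. Some of the fold changes no longer called were about as large with the covariate as without, such as Cidea at 5.95 and 5.81, Lcn2 at 2.22 and 2.28 and Col3a1 at 2.26 and 1.87, while others were smaller, such as Thrsp at 2.59 and 4.33 and Fgf21 at -1.11 and -2.11. Over all 1906 genes the median size of the log2 fold change went from 0.664 to 0.421 and its median SE from 0.157 to 0.296.

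Lipid droplet genes had 8 of 22 higher and 3 lower in Flpo, 8 and 5 adjusted over the list alone (camera, adjusted p = 0.0124, and adjusted p = 0.34 with an estimated correlation). Cfd was higher by 3.45 on the log2 scale (SE 0.37, adjusted p = 2.3e-05), and Cidea, a lipid droplet fusion protein, by 5.81 (SE 0.66, 6.49e-05), a call lost with voom quality weights (adjusted p = 0.0554). Lipogenesis had 8 of 24 higher and 2 lower, 9 and 2 adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.34 with an estimated correlation), with Pklr at 1.49 (SE 0.25, adjusted p = 0.00101). Gluconeogenesis and glycogen had 7 of 22 higher and 2 lower, 9 and 3 adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.34 with an estimated correlation). Of these Pcx was higher (0.55, SE 0.09, adjusted p = 0.000952) and Pck1 lower (-0.86, SE 0.24, 0.0241), a call lost without Cre replicate 1, without Cre replicate 5 or with no low-count filter (adjusted p = 0.0628, 0.051 and 0.0659). Fatty acid oxidation had 7 of 37 lower and 1 higher, 10 and 2 adjusted over the list alone (adjusted p = 0.0321, and adjusted p = 0.772 with an estimated correlation). That call was lost under the replicate block and without Cre replicate 4, Cre replicate 5 or Flpo replicate 4, at adjusted p up to 0.265, and the list's median of -0.13 became 0.00 with library totals alone and 0.08 on log2(TPM + 1). Ehhadh was lower in Flpo by -1.88 (SE 0.26, adjusted p = 0.000188) and Hadh higher by 0.65 (SE 0.10, 0.000362).

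Insulin and growth hormone signalling had 11 of 27 lower and 3 higher in Flpo, 12 and 3 adjusted over the list alone (adjusted p = 0.0039, and adjusted p = 0.149 with an estimated correlation). Igfbp2 stood at -2.08 (SE 0.21, adjusted p = 1.45e-05), Enho at -2.22 (SE 0.33, 0.000442) and Grb14 at -0.66 (SE 0.08, 5.81e-05). Male-biased genes had 18 of 24 lower and 0 higher, 21 and 0 adjusted over the list alone (adjusted p = 6.27e-19, and adjusted p = 0.293 with an estimated correlation). Female-biased genes had 7 of 17 higher and 0 lower, 10 and 1 adjusted over the list alone (adjusted p = 5.57e-06, and adjusted p = 0.319 with an estimated correlation). Cyp2b9 stood at 241 ± 108 against 4.61 ± 5.37 CPM and Hao2, a hydroxyacid oxidase, at 5.46 ± 3.95 against 0.0499 ± 0.0504.

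The circadian clock list had 11 of 20 higher and 4 lower in Flpo than in Cre, 11 and 5 adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.319 with an estimated correlation). Per3 stood at 20.1 ± 4.57 against 3.44 ± 2.66 CPM and Tef at 171 ± 25.5 against 72.5 ± 24.1. Arntl was lower, at 1.79 ± 0.511 against 8.42 ± 4.30. Xenobiotic metabolism had 10 of 23 higher and 0 lower, 11 and 0 adjusted over the list alone (adjusted p = 0.000888, and adjusted p = 0.34 with an estimated correlation). The cell cycle had 3 of 25 higher and 1 lower, 4 and 1 adjusted over the list alone (adjusted p = 0.0153, and adjusted p = 0.319 with an estimated correlation). Oxidative phosphorylation had 2 of 30 higher, 1 adjusted over the list alone (adjusted p = 0.0153, and adjusted p = 0.736 with an estimated correlation), with Sdha, a subunit of complex II, at 0.43 (SE 0.07, adjusted p = 0.000557). The last call was lost under the replicate block and without Cre replicate 4 or Flpo replicate 2, 5 or 6, at adjusted p up to 0.172.

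**Figure D4:**
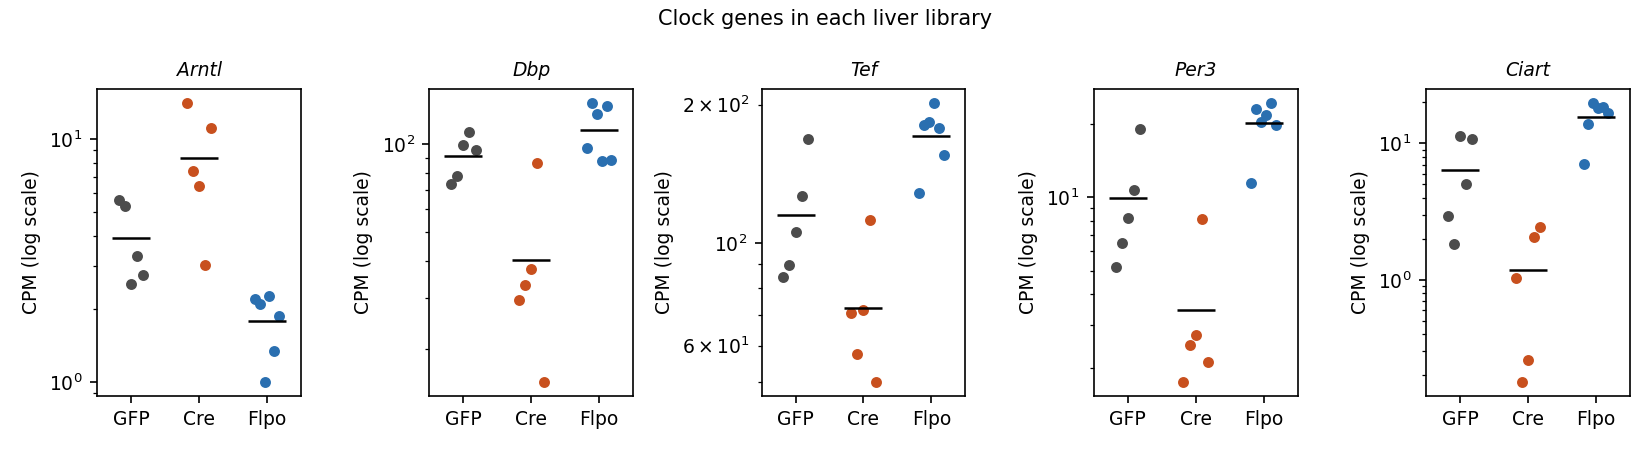
Abundance of 5 clock genes in each liver library, in CPM on log axes, with points for libraries and lines for group means of 5 GFP, 5 Cre and 6 Flpo libraries. Mean Arntl falls from Cre (8.42 ± 4.30 CPM) through GFP (3.92 ± 1.46) to Flpo (1.79 ± 0.511), and the other genes go the other way.

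Among markers of other cell types, stellate cell and fibrosis genes had 10 of 31 higher and 0 lower in Flpo than in Cre, 11 and 0 adjusted over the list alone (adjusted p = 1.25e-05, and adjusted p = 0.34 with an estimated correlation). Kupffer cell markers passed upward with 1 of 16 higher by either adjustment (adjusted p = 0.019), and endothelial markers downward with 1 of 23 lower by either adjustment (adjusted p = 0.019), each at an adjusted p of 0.714 with an estimated correlation. The Kupffer call was lost without Cre replicate 4 and the endothelial call without Cre replicate 1, Cre replicate 5 or Flpo replicate 2, at adjusted p up to 0.1 and 0.101, and the endothelial median of -0.20 became 0.01 on log2(TPM + 1). Lists that did not pass also held members that changed, to be read beside the 13.7% of all genes called in this comparison. In the JNK pathway 3 of 19 were higher by either adjustment (adjusted p = 0.926), among them the JNK phosphatase Dusp1 at 0.87 (SE 0.21, adjusted p = 0.00952). In the AP-1 list 4 of 17 were lower and 1 higher by either adjustment (adjusted p = 0.237), with Egr1 at -2.59 (SE 0.49, adjusted p = 0.00254) and Junb at -1.57 (SE 0.37, 0.0101). Junb turned to 0.03 with the clock score as a covariate. For Egr1, Cre replicate 1 stood at 101.5 CPM against 9.85 to 31.0 in the other Cre libraries. Its log2 fold change ranged from -2.84 to -1.64 over 29 settings without a clock score. The acute phase list had 6 of 27 higher and 3 lower, 6 and 5 adjusted over the list alone (adjusted p = 0.392), with Lcn2 at 2.28 (SE 0.22, adjusted p = 7.99e-06), and the lipoprotein list had 3 of 24 higher and 3 lower, 5 each adjusted over the list alone (adjusted p = 0.815), with Apoa1, the main protein of high-density lipoprotein, at -0.89 (SE 0.14, adjusted p = 0.000346).

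Of the remaining lists in Flpo against Cre, members higher and lower were 6 and 4 of 26 for bile acids (7 and 5 adjusted over the list alone), 2 and 4 of 28 for the stress response (2 and 4), 5 and 2 of 25 for NRF2 (6 and 2) and 3 and 3 of 20 for lipid-associated macrophages (6 and 3). Their adjusted p were 0.926, 0.173, 0.0935 and 0.115. The stress response passed without Flpo replicate 1, NRF2 without Cre replicate 1 or Flpo replicate 1, and the macrophage list without Cre replicate 2 or Flpo replicate 3, at adjusted p down to 0.0358, 0.0354 and 0.0297. With no low-count filter NRF2, the macrophage list and cholesterol synthesis passed (adjusted p = 0.0292, 0.0399 and 0.0462). Cholesterol synthesis, with 1 higher and 1 lower of 25 by either adjustment (adjusted p = 0.0895), also passed without Cre replicate 2, Cre replicate 3 or Flpo replicate 2, 3 or 5, at adjusted p down to 0.00553. Transcripts of blood, pancreas and fat, with 0 of 6 called (adjusted p = 0.116), passed without Cre replicate 2 or Flpo replicate 1, at adjusted p down to 0.028. Median, mean and test differed in sign for the JNK pathway (-0.07, 0.04, up), lipoprotein (-0.06, 0.08, down) and interferon (-0.21, -0.05, up) lists. The macrophage gene Adgre1 was not called (0.72, SE 0.25, adjusted p = 0.063), and passed in 5 of 29 settings, including those without Cre replicate 5 or Flpo replicate 2 (adjusted p = 0.0312 and 0.012). With the clock score, which is not among the 29, Adgre1 did not pass (log2 fold change 0.67, adjusted p = 0.936).

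The comparisons with GFP shared 1 gene called in the same direction, Rec8, which was at 1.70 ± 0.767 CPM in Cre. Independent lists of these sizes share 0.223 genes downward and 0 upward, and 50 draws of simulated unchanged groups against the same controls share 0. The fold changes of the 13905 genes had a correlation across genes of 0.285, and genes are not independent replicates. Simulated unchanged groups gave 0.521. The covariance was 0.0644, against 0.0499 in the simulations (0.044 to 0.0577), a difference of 0.0145. With the GFP libraries split 3 and 2 in all 10 ways, the mean overlap in the same direction was 0, the mean correlation 0.0912 and the mean covariance 0.0384 (0.00756 to 0.0634).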

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

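The test for single libraries far from their group was fixed beforehand, as Dixon's test at its 95% critical value. It was run in each group on 67 of the genes that the text names or plots, a set settled after values were seen, and on 6 library measures. Of 219 groups tested 17 had such a library. For independent and normally distributed values chance gives about 1 in 20, or 10.95. The genes share libraries and their CPM values were not put on a log scale, so that number is only a rough guide. Of the 17, 1 was in GFP, 11 in Cre and 5 in Flpo.

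In each case below 1 library stood apart from the rest of its group, with values in CPM. Cre replicate 4 stood above the other Cre libraries for Thrsp (21.1 against 8.26 to 9.66), Sult2a7 (1.504 against 0.597 to 0.826), Per3 (8.15 against 1.75 to 2.72) and Hmgcs1 (543 against 253 to 336). Cre replicate 5 stood above the others for Ehhadh (3485 against 875 to 1544), Cyp4a31 (155 against 43.0 to 74.9), Ppara (192 against 97.1 to 122) and Adgre1 (6.59 against 3.77 to 4.33). Cre replicate 1 was highest for Ccl2 (0.787 against 0.353 to 0.467), Egr1 (101.5 against 9.85 to 31.0) and Junb (97.9 against 20.7 to 42.9).

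In GFP, replicate 4 was highest for Plin4 (74.4 against 38.3 to 48.3). In Flpo, replicate 1 was lowest for Per3 (11.5 against 19.7 to 24.4) and highest for Hbb-bt (42.7 against 15.5 to 23.1). Flpo replicate 4 was highest for Ccl2 (1.36 against 0.365 to 0.733), Flpo replicate 5 for Gsta1 (7.70 against 2.25 to 3.90) and Flpo replicate 3 for Marco (28.2 against 2.89 to 11.6).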

How the results depend on the processing

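The length and GC offset, the removal of abundant genes and both clock scores were chosen after seeing the data, and the other settings were planned. Counts of changed genes moved by over 1.5 times in these settings, and the cause was not tested except for stricter thresholds, which lower counts by construction. For Cre against GFP the count of 1328 became 834 with only these groups in the fit, 2097 with log2(TPM + 1), 238 with the clock score, 170 with a first score of 10 clock genes picked after their values were seen, 475 at an adjusted p under 0.01 and 822 with a 1.5-fold minimum. In Flpo against GFP the 4 genes became 69 with DESeq2, 2 with limma-voom, 24 with quality weights, 1 with only these groups, and 0 with either clock score, with the replicate block or at 0.01. For Flpo against Cre, 1906 became 8 and 6 with the clock scores, 881 at 0.01 and 1118 with a 1.5-fold minimum. Leaving out 1 library gave 960 to 1462, 0 to 15 and 1454 to 2189 genes. The single gene shared by both comparisons with GFP became 0 with the block and at 0.01, and 0 to 4 without 1 library.

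The list tests that passed, 13, 8 and 14 of 30, became 0, 0 and 0 with an estimated correlation and 8, 0 and 10 with fry, and were 16, 8 and 17 with no low-count filter. Without 1 library they ranged over 11 to 14, 4 to 10 and 11 to 17. The interferon response list in Flpo against Cre passed in the opposite direction without Cre replicate 5 (adjusted p = 0.0389, with 0.0389 to 0.891 over 19 refits and 0.9 as reported).

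Mapk9 in Flpo against Cre, at a log2 fold change of 0.48, passed the threshold with library totals (0.62), quality weights (0.49), only these groups (0.47), 1 surrogate variable (0.47) and log2(TPM + 1) (0.65), and ranged from 0.43 to 0.58 without 1 library. In Cre against GFP it ranged from -0.52 to -0.18. Mapk8 ranged over -0.16 to 0.08 in Cre against GFP and 0.15 to 0.37 in Flpo against Cre without 1 library. Among named genes called as reported, fold changes turned sign with a clock score for Junb (0.0345 and 0.11), Ier2 (0.00998, first score) and Spp1 (-0.0329, first score), all in Flpo against Cre.

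Over all named genes and settings other than leaving out a library, 3439 results kept their side of the threshold, 449 no longer passed, 52 newly passed and 4 called ones turned sign. With 1 library left out the counts were 4010, 202, 28 and 0. Most of the 449 losses came with the clock score and the first clock score. These lost 50 and 57 of 83 called genes in Cre against GFP, and 94 and 92 of 98 in Flpo against Cre. The largest loss in another of those settings was 15 in Cre against GFP, with limma-voom, and 12 in Flpo against Cre, with the replicate block. Some fold changes not called either way, such as Cyp7a1 and Fasn in Cre against GFP with the clock score, also turned sign and are among those that kept their side. The block, fitted without Flpo replicate 6, changed counts to 1019, 0 and 1352. The replicate numbers share only a number: 1 of 15 same-numbered pairs had a correlation over 0.1, and 3 of 15 libraries correlated best with their own number. At this depth and group size 35.8% of simulated 1.5-fold changes among 13615 genes were recovered for Cre against GFP, and depth itself was not varied.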

Other observations

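The tests of time of day, of Xist and Ddx3y counts, of the Mup paralogs and of the clock medians were chosen after the result was seen, as were the families described first. Among 215 families of genes with a shared symbol stem and at least 8 measured members, the annexins (Anxa) fell in Cre against GFP, with 6 of 11 lower (camera, adjusted p = 0.000319, and adjusted p = 0.883 with an estimated correlation). In Flpo against Cre 4 of the 11 were higher (adjusted p = 0.000195, and adjusted p = 0.827 with an estimated correlation). Annexins bind membrane lipids in the presence of calcium. The carbonic anhydrases (Car) had 4 of 9 lower in Cre than in GFP (adjusted p = 0.00359) and 4 higher in Flpo than in Cre (adjusted p = 0.00566), with the same p values as the annexins with an estimated correlation. Proteasome subunits of the Psmd family had 4 of 14 higher in Cre than in GFP (adjusted p = 0.017, and adjusted p = 0.883 with an estimated correlation), and 0 higher with library totals alone or on log2(TPM + 1). The families were not fixed beforehand, so these counts describe these libraries only.

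In 100 drawn splits of the libraries into groups of the same sizes, only the real split of Cre and GFP gave as many as 1328 genes (1 of 100, highest other 3), and only that of Flpo and Cre as many as 1906 (1 of 100, highest other 37), so chance can be excluded for both. For Flpo and GFP 3 of 100 splits gave 4 genes or more, the real one included. That share lies under the limit set beforehand, but other splits called as many genes or more, so chance cannot be excluded for these 4 genes. The highest of the other splits, with GFP replicates 1 to 4 and Flpo replicates 1 and 2 on one side, called 22 genes. That is several times the real count and points to some structure of the samples. The split still set GFP replicates 1 to 4 apart from Flpo replicates 3 to 6, so it was not free of the group difference. The side with GFP replicates 1 to 4 lay at -12.9 to -3.74 on the first principal component, and the other at -20.8 to -15.6. Its score of male-biased minus female-biased genes was -1.11 to 0.354, against -1.77 to -1.30. These values were looked up after the split was seen, and a cause was not tested. The 4 genes became 0 without GFP replicate 1, GFP replicate 2 or Flpo replicate 3, 4 or 6. They also became 0 with the replicate block, which itself left out Flpo replicate 6.

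The first pattern weighed is the large number of genes that differ between Cre and both other groups. Bias by gene length or GC content is argued against. With an offset for it, 90.8% of the genes called in Cre against GFP stayed called in the same direction. Leaving out the most abundant genes and all Mup genes kept 99.7% of the 1308 other called genes. For calls under TMM scaling this argues against the counts taken by those genes as the source. A wider composition effect stays open. That removal hardly changed the TMM scaling, so it could not decide which scaling is right. The median log2 fold change of all genes in Cre against GFP was 0.0014 before it and 0.0022 after. With library totals alone the median was -0.14, and 300 genes were higher and 1656 lower. Time of day at harvest cannot be told apart from the group: with the clock score as a covariate the median adjusted log2 fold change kept 89.2% of its size in Cre against GFP and 64.9% in Flpo against Cre. Calls ended mainly as errors grew and sizes shrank, with a median size of 0.718 and SE of 0.165 before and 0.620 and 0.207 after in Cre against GFP, and 0.664 and 0.157 before and 0.421 and 0.296 after in Flpo against Cre. An effect of the 7a isoforms, of Cre recombinase itself, or of the batch of animals stays open and was not tested.

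The second pattern is that 19 of 24 male-biased genes were higher and 6 of 17 female-biased genes lower in Cre than in GFP. Female animals are argued against, as the highest Xist count was 3 and the lowest Ddx3y count 1216 among the 16 libraries, and reads shared among Mup paralogs do not carry the pattern, as 13 of the 16 male-biased genes outside that family (81.25%) were called higher. Whether sex-biased genes follow lipid droplet genes from library to library stays open. The lipid droplet score used only the 7 list members called lower in Cre than in GFP, so it was picked from these data. Over the 16 libraries centred on their group means, Pearson's r was 0.130 (permutation p = 0.653, adjusted p = 0.653 over 3 relations, interval -0.430 to 0.618). Spearman's rho was 0.218 (permutation p = 0.456, adjusted p = 0.791) and r without the 2 farthest libraries was 0.0675. An effect of the isoform group and an exchange of male animals or tubes stay open and were not tested.

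The third pattern is the order of clock genes by group, with GFP between Cre and Flpo, which single libraries did not all keep: the clock score was -0.042 in Cre replicate 4 (-2.47 to -1.86 in the other Cre libraries), above GFP replicates 1 and 2 (-1.11 and -1.12), and 0.591 in Flpo replicate 1, below GFP replicates 4 and 5 (0.626 and 1.03). The median log2 fold change of 10 clock genes of the day phase minus that of 4 of the night phase was -1.02 in Cre against GFP and 1.51 in Flpo against GFP. A difference in time of day or of clock phase would give such opposite shifts. Camera passed the clock list only in the latter comparison (adjusted p = 0.283 and 0.00265), with 0 of its 20 members called there. Camera tests for a shift in 1 direction, so genes of opposite phase can cancel, and these p values do not decide whether the clock differs. The day gene Nr1d1, singled out after its values were seen, had signs opposite to the day-phase medians, at 0.44 in Cre (adjusted p = 0.397) and -0.79 in Flpo (adjusted p = 0.404), against GFP. Library quality stays open, as the score's correlation with the mitochondrial share was r = 0.232 (permutation p = 0.430, rho = 0.0765, p = 0.791, r without the 2 farthest libraries -0.119) and with the library total r = 0.174 (permutation p = 0.491, rho = 0.0912, p = 0.736, r without the 2 farthest 0.2003), at adjusted p of 0.653 for r and 0.791 for rho over 3 relations. The labels used here give no harvest time, so a feeding or harvest difference and a direct effect of the isoforms on the clock cannot be told apart.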
